A study of Mus musculus with 10 samples.

How the data were processed

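Total RNA from frozen, powdered inner ear tissue was labelled with biotin by the Affymetrix WT PLUS kit, per the labels' protocols, and put on 1 array per sample. The values are log2 expression per transcript cluster as deposited by the authors. RMA, which corrects background, normalizes by quantiles and summarizes probes, and the Partek software are named per the submitters' processing notes, without versions. The chip, the genome build and any filter are not given in the sources used here, so no coordinates are printed. Quantile normalization makes array distributions nearly equal, so a change shared by most genes cannot be seen, and RMA values of dim genes understate fold changes.

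Of 39295 probe sets, 30130 had 1 gene symbol in the platform annotation, 2146 several and 7019 none. For 827 probe sets the symbol was updated through its Entrez identifier to the name in NCBI RefSeq (assembly GRCm38.p6, used for names only). Probe sets with 1 symbol were used, and of several for a gene (294 genes) the one with the highest mean over the 10 arrays, which left 29766 genes. No probe set with several symbols or none passed when every one was tested (smallest adjusted p = 0.397 and 0.177).

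Samples were grouped by their labels, 5 with a wheel and 5 without. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided, Benjamini-Hochberg adjustment, threshold adjusted p under 0.05). Differences are runner minus control on the log2 scale with the moderated standard error, and for a list the mean of its genes per array with the standard error of the difference in means. Fold is 2 to the power of the size of the log2 difference. Replicates were compared by correlation before averaging. Principal components were computed from all genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

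Gene lists of cell types, tissues and processes were tested, 29 in all, and a list of sex-linked genes was given as values. Together they had 451 members, of which 415 were measured by a probe set with 1 symbol. The tested lists were hair cells, supporting cells, stria vascularis, spiral ligament fibrocytes, spiral ganglion neurons, myelinating glia, endothelium and pericytes, macrophages, B lineage, T and NK cells, neutrophils, erythroid cells, bone, skeletal muscle, middle ear and airway epithelium, brain and choroid plexus, adipocytes, complement, antigen presentation, interferon-stimulated genes, inflammatory cytokines and chemokines, angiogenesis and hypoxia, oxidative phosphorylation, exercise and mitochondrial regulators, antioxidant defence, immediate early and stress genes, circadian clock, cell cycle and extracellular matrix. Each was tested by camera with a preset correlation of 0.01 between genes, again with the correlation estimated, by fry, and by an exact permutation test of the list mean over all 252 assignments of arrays. The smallest p this permutation test can give is 0.00794. Camera compares a list with all other genes, whereas fry does not. Counts adjusted over the list alone apply the Benjamini-Hochberg method within the list.

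The tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, of the genes past the threshold, the 8 with the largest rise and the 8 with the largest fall, filled up to 8 by the smallest unadjusted p. It also took the 4 members with the smallest p of each list called by camera, 2 of each other list, and the sex-linked genes. Predicted and non-coding symbols and large multigene families were counted but not named. The rule gave 110 genes.

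Both tests were tested on simulated data with the size and spread of these arrays. Of 100 genes changed by 0.5 log2 the gene test recovered 79%, of 100 changed by 1 log2 97%, with 3 false calls among 29766 genes. These genes varied independently of each other and 200 were changed, so recovery may be lower in the real arrays. A list shifted by 0.3 log2 was called by camera, with 0 of the others called, but the simulated genes were uncorrelated.

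Alternatives were a filter on dim genes, trended and robust moderation, no moderation, repeated quantile normalization, median centring, array weights, the mean of all probe sets of a gene, every probe set, a replicate block, other thresholds, the 5000 genes of highest variance for the principal components, and each array left out in turn. Sex was not given in the labels. A sex covariate was to be fitted only if sex-linked genes fell into separate clusters, and it was not fitted because all 10 arrays fell into 1.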

Results

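Gene expression was measured with 1 microarray per sample in the cochlea, the hearing organ of the inner ear, of 6-month-old CBA/CaJ mice with normal hearing. All mice were housed singly, 5 samples from cages with a running wheel (runners) and 5 from cages without one (controls). The series is about long-term voluntary running and hearing loss with age, and these arrays address how the young cochlea differed with a wheel in the cage. The median log2 value per array over the genes tested lay between 5.35 and 5.43. Named genes of other tissues were bright. In controls Gabra6 of the brain list was at 10.6, Alas2 of the erythroid list at 9.80, Ly6g of the neutrophil list at 9.22 and Myh1 of the muscle list at 9.19. The mean of the hair cell list was 5.34. The samples may thus hold brain, marrow and muscle beside cochlea, and a change need not lie in the cochlea itself. Pearson correlations across the 29766 genes tested were 0.995 to 0.997 within controls, 0.991 to 0.997 within runners and 0.992 to 0.996 between groups, so no 2 arrays were identical. The number of arrays limits the precision of every value given here. The labels do not say that each array came from a separate animal, so p-values measure the spread between these samples, which may be technical.

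Bglap and Bglap2, which encode the bone matrix protein osteocalcin, were lower in the samples of runners and were the 2 genes of 29766 that passed the test. Bglap had a log2 level of 8.35 ± 0.07 (SD, n = 5) in controls and 7.50 ± 0.12 (SD, n = 5) in runners, a difference of -0.85 ± 0.066 (SE) or 1.80-fold (limma adjusted p = 0.000402). Bglap2 had 9.01 ± 0.12 (SD) in controls and 8.06 ± 0.15 (SD) in runners, a difference of -0.95 ± 0.083 (SE) or 1.93-fold (limma adjusted p = 0.000806). All 5 runners lay below all 5 controls for both. Bglap and Bglap2 are near-identical copies whose probes can bind the same transcripts, so it is uncertain whether these are separate signals. Without moderation of the variance Bglap2 no longer passed (adjusted p = 0.0750), the highest of its alternatives, which began at 0.000249.

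No gene was higher in runners at a limma adjusted p under 0.05, and 955 genes were higher and 1168 lower at an unadjusted p under 0.05, 7.13% of genes. With predicted and non-coding symbols and large multigene families left out, the 8 genes with the smallest p among those higher in runners did not pass. They were the transcriptional repressor Bcl6 (log2 difference 0.51 ± 0.084 SE), Angptl4, an inhibitor of lipoprotein lipase (0.33 ± 0.054), Fam107a (0.39 ± 0.065), the glutamate carboxypeptidase Folh1 (0.38 ± 0.072) and the fatty acid elongase Elovl3 (1.04 ± 0.20). Fasn, the fatty acid synthase (0.69 ± 0.14), the kinase Stk32a (0.50 ± 0.10) and the cell cycle inhibitor Cdkn1a (0.32 ± 0.067) complete them, with adjusted p between 0.141 and 0.370. Lower in runners without passing were the B cell genes Fcrla (-0.71 ± 0.11), Cd72 (-0.62 ± 0.098), Cd79b (-0.66 ± 0.11) and Niban3 (-0.55 ± 0.093), the histone gene H2bc3 (-0.35 ± 0.056) and Il2ra (-0.48 ± 0.078), a chain of the interleukin 2 receptor, each at adjusted p = 0.141. Runner 1 decided these counts: without it 44 genes were higher and 55 lower, among them Bcl6, Elovl3, Fasn, Fcrla, Cd72 and Cd79b. Without runner 1 and control 1, an alternative chosen after the data were seen, 134 genes were higher and 292 lower. Over those 426 genes runner 1 lay at -0.020 and control 1 at 0.51, where 0 is the mean of the other controls and 1 that of the other runners. The groups did not overlap for 276 genes, or 0.927%, where chance gives 0.794%. The first principal component held 28.2% of the variance and its scores differed by 6.37 ± 9.32 (SE), less than the spread between arrays (exact permutation p = 0.5, two-sided).

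**Figure D1:**
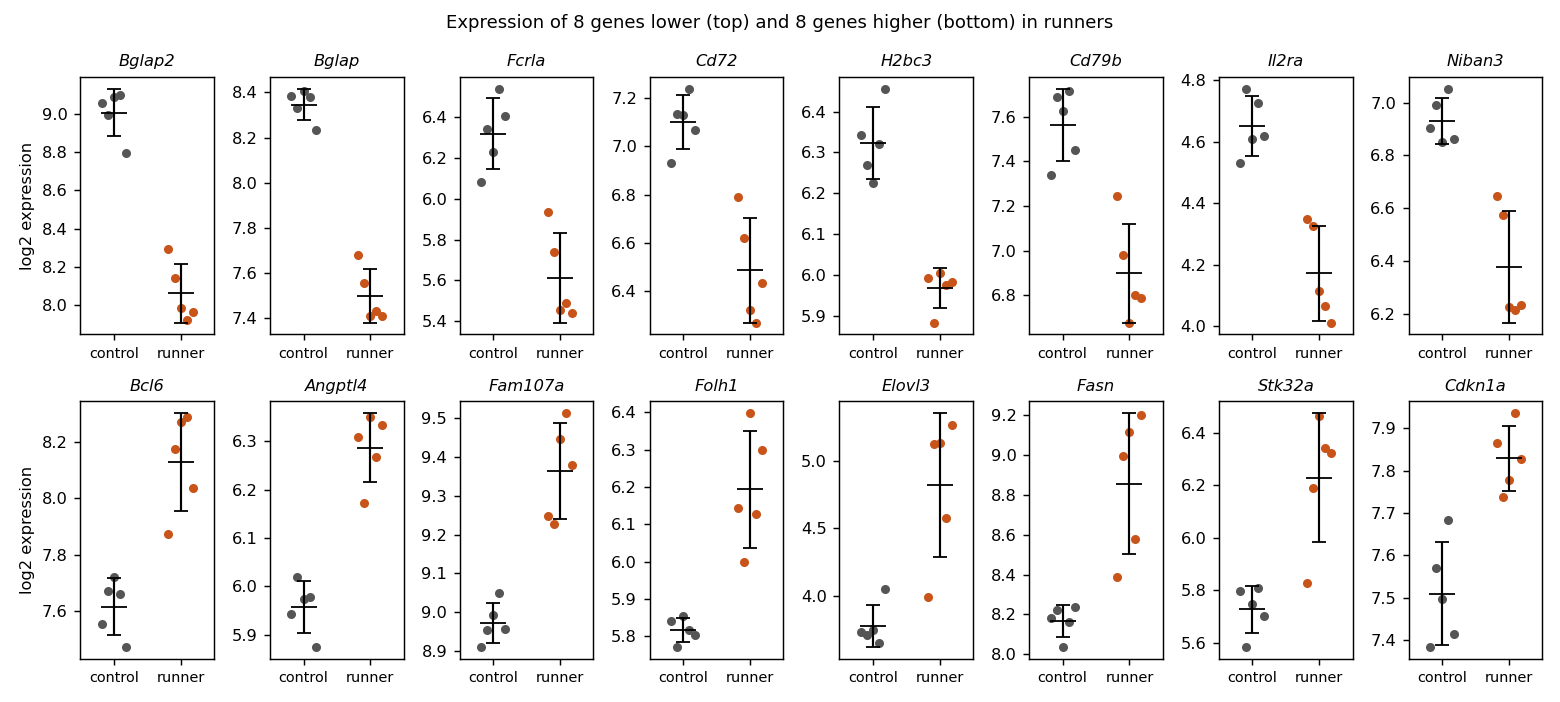
Log2 expression of 16 genes in 5 control and 5 runner arrays. Points are arrays, and the black mark and bar are the mean and SD of each group. In Bglap and Bglap2, the 2 genes that passed, every runner lies below every control.

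Most bone and matrix genes were lower in runners. Of 15 measured genes of bone cells and bone matrix, 12 were lower, 7 at an unadjusted p under 0.05, 6 adjusted over the list alone and 2, Bglap and Bglap2, over all genes. Col1a1 and Col1a2, the chains of type I collagen, had differences of -0.61 ± 0.11 and -0.45 ± 0.086 (SE). The mean of the 7 osteoblast genes of the list differed by -0.50 ± 0.078 (SE). A set of 16 osteocyte and osteoclast genes, drawn up later and partly in the list, differed by -0.063 ± 0.050 (SE; exact permutation p = 0.246). The mean of the whole bone list differed by -0.26 ± 0.067 (SE; exact permutation p = 0.0159, adjusted 0.115). The list was called lower by camera (adjusted p = 3.85e-09), but not with an estimated correlation (adjusted p = 0.198 with an estimated correlation). Of 15 extracellular matrix genes, which share Col1a1 and Col1a2 with the bone list, 13 were lower, 8 at an unadjusted p under 0.05, 8 adjusted over the list alone and 0 over all genes. Among them were Col11a1 (-0.35 ± 0.081) and Col5a2 (-0.26 ± 0.064). The extracellular matrix mean differed by -0.21 ± 0.054 (exact permutation p = 0.00794, the smallest these groups can give, adjusted 0.115). This list was also called by camera (adjusted p = 2.18e-09; adjusted p = 0.198 with an estimated correlation).

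Genes of the B lineage were lower in runners as a group, though the list mean was 6.25 in runner 1 and 6.18 in control 1. All 16 measured members were lower, 14 at an unadjusted p under 0.05, 13 adjusted over the list alone and 0 over all genes. Fcrla and Cd79b, a chain of the B cell receptor complex, led them, followed by the kinase Blk (-0.42 ± 0.073) and Vpreb3 (-0.47 ± 0.090), a gene of early B cells. The mean of the list was 6.39 ± 0.15 (SD) in controls and 5.96 ± 0.22 (SD) in runners, a difference of -0.43 ± 0.12 (SE; exact permutation p = 0.0159, adjusted 0.115). Camera called it lower (adjusted p = 3.48e-20; adjusted p = 0.198 with an estimated correlation). Runner 1 lay 0.37 above the mean of the other runners in this list and control 1 lay -0.25 from that of the other controls.

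Adipocyte genes were higher in runners. All 8 measured members were higher, 6 at an unadjusted p under 0.05, 6 adjusted over the list alone and 0 over all genes. Examples were the fatty acid carrier Fabp4 (0.53 ± 0.12), the lipid droplet protein gene Cidec (0.73 ± 0.18), Retn, which encodes resistin (0.49 ± 0.14), and Pck1, a gene of glyceride and glucose synthesis (0.49 ± 0.17). The mean differed by 0.36 ± 0.11 (exact permutation p = 0.00794, adjusted 0.115). Camera called the list higher (adjusted p = 7.86e-08; adjusted p = 0.198 with an estimated correlation). Runners 3 and 5 were the highest arrays, at 0.48 and 0.35 above the mean of all 10. Skeletal muscle genes were also highest in runner 3, at 0.53 above that mean.

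The macrophage, neutrophil, erythroid and cell cycle list means were lower in each of runners 2 to 5 than in each of controls 2 to 5, while runner 1 lay high and control 1 low. All 16 macrophage genes were lower, 6 at an unadjusted p under 0.05, 2 adjusted over the list alone and 0 over all genes. The chemokine receptor Cx3cr1 (-0.31 ± 0.061) and Ms4a7 (-0.27 ± 0.080) were the 2, followed by Adgre1 (-0.31 ± 0.11) and the growth factor receptor Csf1r (-0.20 ± 0.071). The macrophage mean differed by -0.21 ± 0.097, and runner 1 lay 0.44 above the mean of the other runners (camera adjusted p = 2.18e-09; adjusted p = 0.275 with an estimated correlation). All 15 cell cycle genes were lower, 5 at an unadjusted p under 0.05 and 0 after either adjustment, with Ccnb2 (-0.31 ± 0.10), Mcm5 (-0.23 ± 0.082), Aurkb (-0.22 ± 0.086) and Kif11 (-0.33 ± 0.14) first (list mean -0.22 ± 0.11; camera adjusted p = 3.85e-09; adjusted p = 0.275 with an estimated correlation). Neutrophil genes, with Ly6g (-0.39 ± 0.12), Prtn3 (-0.24 ± 0.087), Ly6c2 (-0.25 ± 0.11) and Ctsg (-0.22 ± 0.11) first, were lower in 14 of 16, 3 at an unadjusted p under 0.05 and 0 after either adjustment (list mean -0.14 ± 0.12, and -0.24 without runner 1; camera adjusted p = 0.00022; adjusted p = 0.380 with an estimated correlation). Erythroid genes, with Car1 (-0.31 ± 0.12), the heme synthesis gene Alas2 (-0.25 ± 0.10), Slc4a1 (-0.24 ± 0.12) and Klf1 (-0.22 ± 0.11) first, were lower in 11 of 12, 2 at an unadjusted p under 0.05 and 0 after either adjustment (list mean -0.16 ± 0.10; camera adjusted p = 0.000196; adjusted p = 0.310 with an estimated correlation). Runner 1 lay 0.48 above the mean of the other runners in the neutrophil list, 0.33 in the erythroid list and 0.39 in the cell cycle list. Control 1 lay -0.30, -0.25 and -0.30 from the mean of the other controls in these 3 lists and -0.18 in the macrophage list. None of the 4 means differed by the exact permutation test (p = 0.0714 for macrophages, 0.103 for cell cycle, 0.167 for erythroid and 0.254 for neutrophils).

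Antigen presentation and complement lists were called lower by camera beside the macrophage and B lineage lists, but neither mean differed by the exact permutation test (p = 0.0714 each). The complement list shares C1qa, C1qb and C1qc with the macrophage list. All 14 antigen presentation genes were lower, 6 at an unadjusted p under 0.05 and 0 after either adjustment, with B2m (-0.28 ± 0.090), Psmb8 (-0.24 ± 0.084), H2-Aa (-0.19 ± 0.072) and H2-K1 (-0.23 ± 0.098) first. The list mean differed by -0.17 ± 0.079 (camera adjusted p = 2.31e-08; adjusted p = 0.275 with an estimated correlation). Complement genes were lower in 12 of 13, 2 at an unadjusted p under 0.05, 1 adjusted over the list alone and 0 over all genes. The 1 was the C3a receptor gene C3ar1 (-0.35 ± 0.097), before Cfb (-0.17 ± 0.068), C1qb (-0.26 ± 0.13) and Serping1 (-0.14 ± 0.069). The complement mean differed by -0.13 ± 0.061 (camera adjusted p = 3.47e-05; adjusted p = 0.275 with an estimated correlation). Runner 1 lay 0.32 above the mean of the other runners in antigen presentation and 0.26 in complement.

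Hair cell, supporting cell, stria vascularis and spiral ligament lists were called lower in runners by camera, but none of the 4 means differed by the exact permutation test (p = 0.0952, 0.0556, 0.0873 and 0.0635). Spiral ligament fibrocyte genes were lower in 10 of 10, 6 at an unadjusted p under 0.05 and 0 after either adjustment, with Tbx18 (-0.37 ± 0.13), Pou3f4 (-0.35 ± 0.13), the water channel Aqp1 (-0.21 ± 0.080) and Dcn (-0.22 ± 0.088) first (list mean -0.25 ± 0.12; camera adjusted p = 5.06e-07; adjusted p = 0.275 with an estimated correlation). Hair cell genes were lower in 14 of 15, 3 at an unadjusted p under 0.05 and 0 after either adjustment. Among them were oncomodulin, Ocm (-0.32 ± 0.12), prestin, Slc26a5 (-0.21 ± 0.090), Loxhd1 (-0.12 ± 0.053) and Chrna9 (-0.11 ± 0.051), and the mean differed by -0.12 ± 0.060 (camera adjusted p = 1.34e-05; adjusted p = 0.275 with an estimated correlation). Genes of the stria vascularis, the tissue that sets the fluid potential of the cochlea, were lower in 10 of 14, 5 at an unadjusted p under 0.05, 2 adjusted over the list alone and 0 over all genes. The 2 were the tight junction gene Cldn11 (-0.25 ± 0.064) and tyrosinase, Tyr (-0.37 ± 0.11), before Kcne1 (-0.32 ± 0.12) and Dct (-0.32 ± 0.12), and the mean differed by -0.14 ± 0.065 (camera adjusted p = 0.000157; adjusted p = 0.280 with an estimated correlation). Supporting cell genes were lower in 9 of 13, 4 at an unadjusted p under 0.05 and 0 after either adjustment, led by Epyc (-0.52 ± 0.15), Otogl (-0.41 ± 0.15), Sox2 (-0.23 ± 0.094) and Otoa (-0.25 ± 0.11), and the mean differed by -0.17 ± 0.073 (camera adjusted p = 0.00183; adjusted p = 0.198 with an estimated correlation). Runner 1 lay above the mean of the other runners by 0.49 in the spiral ligament list, 0.24 in the hair cell list, 0.24 in the stria list and 0.30 in the supporting cell list.

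Spiral ganglion neuron genes were higher in 13 of 15, 3 higher and 1 lower at an unadjusted p under 0.05, 1 adjusted over the list alone and 0 over all genes. The 1 was Ntng1 (0.29 ± 0.077), with Syt1 (0.28 ± 0.13) and the neurotrophin receptor gene Ntrk3 (0.27 ± 0.12) next, while Calb2 differed by -0.23 ± 0.075. The mean differed by 0.094 ± 0.062 (camera adjusted p = 0.0156; adjusted p = 0.283 with an estimated correlation). This call ended without runner 2 (0.066), runner 4 (0.089) or control 3 (0.077), with repeated quantile normalization (0.097) and with centring of each array on its median (0.12). Gabra6, a gene of cerebellar granule cells from the brain list, was higher in runners 2 to 5 than in every control and lowest in runner 1 (0.24 ± 0.13). Genes of the neuron list such as Snap25 and Syt1 are expressed by neurons in general, so ganglion and carried brain cannot be told apart from it. Circadian clock genes were higher in 11 of 15, 3 at an unadjusted p under 0.05, 1 adjusted over the list alone and 0 over all genes. The 1 was Per2 (0.47 ± 0.11), with Cry1 (0.36 ± 0.14), Tef (0.14 ± 0.059) and Hlf (0.099 ± 0.056) next. The clock mean differed by 0.085 ± 0.044 (camera adjusted p = 0.0122; adjusted p = 0.310 with an estimated correlation), and the call ended without runner 2 (0.058), runner 4 (0.079) or control 3 (0.072). Oxidative phosphorylation genes were higher in 18 of 20, 0 at an unadjusted p under 0.05 in limma and 0 after either adjustment, with Cycs (0.15 ± 0.096), Ndufa4 (0.14 ± 0.10), Uqcrc2 (0.082 ± 0.067) and Sdha (0.074 ± 0.061) first. Their mean differed by 0.052 ± 0.082 (camera adjusted p = 0.0365; adjusted p = 0.688 with an estimated correlation). It was 0.00033 without runner 3, 0.020 without runner 5, 0.036 without control 2, 0.040 without control 5 and 0.056 without control 1, each without a call. It was 0.098 without runner 2, 0.084 without runner 4 and 0.085 without control 3, each with one.

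**Figure D2:**
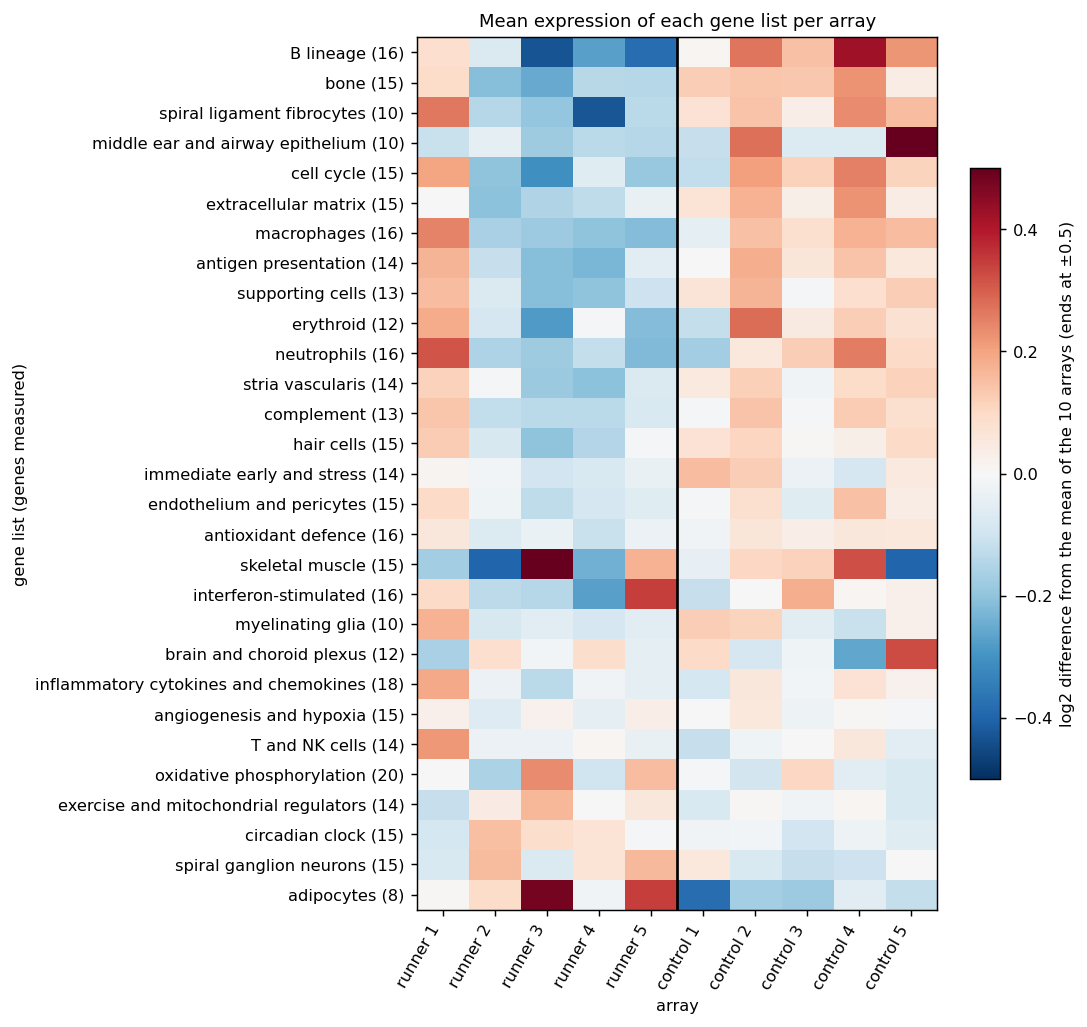
Mean log2 expression of 29 gene lists in 10 arrays, each as the difference from the list's mean over the 10 arrays. Runner 1 lies above the other runners in the macrophage, neutrophil and spiral ligament lists, by 0.44, 0.48 and 0.49 against their mean, and the lists are ordered from lowest to highest difference between runners and controls.

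Endothelial and pericyte genes were lower in 12 of 15 and antioxidant genes in 14 of 16, with 0 members of either at an unadjusted p under 0.05 in limma and 0 after either adjustment. The endothelial list, with Vwf (-0.12 ± 0.065), Emcn (-0.21 ± 0.11), Tie1 (-0.093 ± 0.051) and Cdh5 (-0.13 ± 0.081) first, differed by -0.077 ± 0.052 (camera adjusted p = 0.00621; adjusted p = 0.375 with an estimated correlation). Its call ended without runner 3 (-0.056) or control 4 (-0.050). The antioxidant list, with Gsr (-0.13 ± 0.067), Gpx1 (-0.11 ± 0.066), Hmox1 (-0.19 ± 0.12) and Cat (-0.23 ± 0.18) first, differed by -0.075 ± 0.031 (camera adjusted p = 0.0089; adjusted p = 0.275 with an estimated correlation).

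The 10 other lists were not called by camera. Exercise and mitochondrial regulators were higher in 9 of 14 (mean 0.059 ± 0.050, adjusted p = 0.417), and 1 member passed adjusted over the list alone and 0 over all genes, Pdk4, an inhibitor of glucose oxidation (0.61 ± 0.16). The growth factor gene Igf1 of that list differed by -0.29 ± 0.091. Myelinating glia (mean -0.037 ± 0.067, adjusted p = 0.445; Mobp 0.25 ± 0.094, Cldn19 -0.20 ± 0.14), inflammatory cytokines (-0.018 ± 0.061, adjusted p = 0.671; Il1a -0.28 ± 0.097, Tnf -0.18 ± 0.067) and angiogenesis genes (-0.012 ± 0.024, adjusted p = 0.783; Pdk1 -0.14 ± 0.058, Angpt1 -0.16 ± 0.071) differed by less than their spread. The means of the inflammatory and angiogenesis lists turned above 0 when each array was centred on its median, at 0.0056 and 0.011, and the median of the angiogenesis list was above 0 as tested. T and NK cell genes (0.051 ± 0.056, adjusted p = 0.132; Cd8a 0.17 ± 0.073, Ccl5 0.21 ± 0.10) were called higher without runner 5 (0.067) or control 4 (0.072), but their mean was 0.0038 without runner 1, the highest array. Interferon-stimulated genes (-0.041 ± 0.12, adjusted p = 0.312; Cxcl10 -0.14 ± 0.079, Ifit2 -0.14 ± 0.096) were called lower without runner 5 (-0.13), and their mean was 0.021 without runner 4. Immediate early genes (-0.084 ± 0.049, adjusted p = 0.118; Btg2 -0.17 ± 0.077, Fos -0.56 ± 0.26) were called lower without control 4 (-0.12), with a mean of -0.057 without control 1. Of tissues that border the cochlea, skeletal muscle (-0.042 ± 0.21, adjusted p = 0.561; Tnnc2 -0.15 ± 0.19, Myh1 -0.12 ± 0.19) was called lower without runner 3 (-0.18) or control 5 (-0.15), and its mean turned to 0.052 without runner 2. Middle ear epithelium (-0.24 ± 0.14, adjusted p = 0.0992; Bpifb1 -1.26 ± 0.59, Scgb1a1 -0.12 ± 0.062) was called lower without control 1 (-0.30), but its mean was -0.13 and Bpifb1 -0.68 without control 5, the highest array. Brain and choroid plexus genes (-0.022 ± 0.11, adjusted p = 0.553; Kl -0.38 ± 0.15, Gabra6 0.24 ± 0.13) had a mean below 0 but a median and a camera direction above it, and were called higher without runner 1 (0.017). Their mean was 0.0018 when each array was centred on its median.

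In all, camera called 4 lists higher and 15 lower of 29 with the preset correlation and 0 with an estimated one. Fry's directional test called 0, and its mixed test, for change in either direction, called 3, the bone, extracellular matrix and B lineage lists. By the exact permutation test 4 list means differed at p under 0.05 and 0 after adjustment, with a smallest adjusted p of 0.115. The 15 other lists called by camera had exact permutation p between 0.0556 and 0.540. The Y-linked genes Uty, Kdm5d and Eif2s3y differed by 0.11 ± 0.077, 0.034 ± 0.055 and 0.11 ± 0.064 and Xist by 0.012 ± 0.063, with 1 cluster of arrays in each.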

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

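The tests of exchanged labels and of marrow in runner 1 were chosen after the results were seen. Each group of 5 arrays was searched for an array whose gap to the nearest other, divided by the group's range, exceeded Dixon's critical value of 0.71. Of 270 such groups (named genes and lists in either group) 19 held one, and chance alone gives about 1 in 20. In 13 of the 19 the array was runner 1, the highest of the runners. The ratio was 0.759 for Otoa, 0.815 for Adgre1, 0.856 for Csf1r, 0.775 for Ly6g, 0.731 for Alas2, 0.778 for Serping1, 0.810 for Gsr and 0.832 for Col11a1. For list means of runner 1 it was 0.873 for myelinating glia, 0.887 for macrophages, 0.808 for T and NK cells, 0.813 for neutrophils and 0.784 for complement.

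The other 6 were single genes. Elovl3 was highest in control 5 (0.761) and Cxcl10 highest in runner 5 (0.772). H2bc3 was lowest in runner 2 (0.755), Tyr lowest in control 1 (0.724), Fabp4 lowest in control 1 (0.711) and Psmb8 lowest in control 5 (0.750).

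Chance was weighed by 100 of the 126 splits of the 10 arrays into 5 and 5. Of these, 2 splits, the real one included, gave at least 2 genes past the adjusted threshold. That count was thus uncommon among the splits, but it rests on Bglap and Bglap2, which may be 1 signal, so chance is not excluded. The other split gave 841. That split exchanges runner 1 and control 1, and a count so far above the real 2 points to a difference among the samples that the labels do not follow. For genes at an unadjusted p under 0.05, 26 splits gave at least the real 2123, up to 5142, so chance is not excluded. For lists called by camera, 10 splits gave at least the real 19, up to 22, so chance is not excluded there either.

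Runner 1 was high and control 1 low in marrow and immune genes, which a swap of their labels could produce. Over the 426 genes called in the other 8 arrays, runner 1 lay at -0.020 and control 1 at 0.51 on a scale from 0 (mean of the other controls) to 1 (mean of the other runners). On 426 genes, leaving out another same-number pair put the runner at 0.54 or above and the control at 0.41 or below. Those pairs had helped to pick the genes, and runner 1 and control 1 stood in their scale, so the comparison is not like for like. Against a swap, which needs control 1 near 1, Bglap was 7.68 in runner 1 and 8.38 in control 1, each near its labelled group, and glucocorticoid-induced genes also placed both with their groups. But Bglap was picked, and the glucocorticoid list prompted, by the labelled contrast itself, so they weigh little. Few genes decide this, and a swap is not excluded. More marrow in runner 1 would lower cochlear genes, but the median over hair cell, supporting cell, stria and spiral ligament lists was 0.268 above the other runners, with 0.372 for marrow lists. RNA quality, the share of nerve in the dissected tissue and a true difference between mice were not tested and stay open.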

How the results depend on the processing

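Leaving out runner 1 and control 1 together was chosen after the data were seen; the other alternatives were planned. Bglap and Bglap2 were both called under every alternative of the gene test except no moderation, which called 1 lower (Bglap). Genes higher and lower were 5 and 10 with array weights, 955 and 1168 at an unadjusted p under 0.05, and 134 and 292 without runner 1 and control 1. With 1 array left out they ranged from 0 to 44 and from 2 to 55, and lists higher and lower by camera from 2 to 5 and from 15 to 16. The neuron list was no longer called after repeated quantile normalization or centring. Lists higher and lower were 0 and 0 with an estimated correlation and 0 and 0 by directional fry, and 3 changed by mixed fry against 19. The cause was not tested, apart from the correlation between genes that the estimated correlation and fry take in. Of the named genes 22 passed anew without runner 1, and 13 list calls were lost over all arrays left out in turn. The group difference of the first principal component stayed short of the threshold, at 0.804 to 13.1 with 1 array left out.

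Means reversed, all without a call unless said. Without dim genes the inflammatory list was 0.0060. With centring it was 0.0056, brain and choroid plexus 0.0018 and angiogenesis 0.011. With array weights Tnnc2 was 0.015, Myh1 0.020, Xist -0.0069 and skeletal muscle 0.086. Without runner 1 and control 1, Xist was -0.017, T and NK cells -0.018 and brain and choroid plexus 0.038, the last called. With 1 array left out, Xist ranged from -0.036 to 0.037, Myh1 from -0.25 to 0.0026, brain and choroid plexus from -0.089 to 0.057 (0.017 and called without runner 1), skeletal muscle from -0.18 to 0.052, angiogenesis and hypoxia from -0.022 to 0.0026, inflammatory cytokines and chemokines from -0.068 to 0.014, interferon-stimulated from -0.13 to 0.021. The cause was not tested.

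The replicate numbers did not pair the samples: same-number correlations ran from -0.25 to 0.28, 1 of 5 exceeded 0.1, and 1 of 10 samples matched its own number best. With the replicate block 0 genes were higher and 2 lower, and 4 lists higher and 15 lower. Dim genes lie near background, where arrays understate differences.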

Other observations

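The gene lists in this part were drawn up after the main results were seen, and the tests of less bone and of less marrow were chosen after the results they bear on were known. Genes of lipid synthesis were higher in runners in 12 of 12 measured members, 6 at an unadjusted p under 0.05, with Scd1 (0.57 ± 0.13), Thrsp (0.52 ± 0.12) and Dgat2 (0.45 ± 0.13) beside Fasn and Elovl3. The list mean differed by 0.37 ± 0.10 (SE; exact permutation p = 0.0159), and by 0.27 ± 0.080 without Fasn and Elovl3, which had prompted the list (exact permutation p = 0.0317). The rise was not seen in runner 1. Against the mean of all arrays its lipid synthesis mean lay at -0.15, within the controls (-0.25 to -0.11), with runners 2 to 5 at 0.087 to 0.36. Of 6 brown fat genes, Elovl3, which prompted that list, differed by 1.04 ± 0.20 and Ucp1, the uncoupling protein gene, by 1.93 ± 0.54, while Cidea, Cox8b, Dio2 and Pparg differed by 0.38 ± 0.20, -0.12 ± 0.14, 0.055 ± 0.067 and -0.020 ± 0.083. The mean of the 6 differed by 0.55 ± 0.21 (exact permutation p = 0.0397), and by 0.45 ± 0.21 without Elovl3 (exact permutation p = 0.0873), most of it from Ucp1. For the 6, runner 1 lay at -0.31 from the mean of all arrays, within the controls (-0.57 to -0.017), with runners 2 to 5 at 0.0043 to 0.61. Megakaryocyte and platelet genes were lower in 6 of 6, among them Ppbp (-0.39 ± 0.076) and Pf4 (-0.31 ± 0.080), with a list mean of -0.33 ± 0.096 (exact permutation p = 0.0159). None of these genes passed the adjusted threshold over all genes in limma.

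Genes known to be induced by glucocorticoids, the adrenal stress hormones, were higher in runners in 17 of 18, 12 at an unadjusted p under 0.05 and 0 over all genes in limma. Examples were Zbtb16 (0.48 ± 0.14), Fkbp5 (0.47 ± 0.11), Mt2 (0.42 ± 0.12), Tsc22d3 (0.34 ± 0.087) and Klf9 (0.32 ± 0.078). The list was chosen without Bcl6, Angptl4, Fam107a and Cdkn1a, whose values had been seen, and 2 of its 18 genes, Per1 and Pdk4, also stood in lists of the report. Its mean difference lay between 0.23 and 0.29 with any 1 array left out.

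Lower bone matrix and B lineage genes were the clearest pattern, weighed against less bone or marrow in the runner samples. For less bone, the 7 osteoblast genes of the bone list minus 16 osteocyte and osteoclast genes differed by -0.44 ± 0.040 (exact permutation p = 0.00794). The 7 hold Bglap, Bglap2, Col1a1 and Col1a2, already seen to fall, so this p-value is no independent support. The 16 had a median of -0.047 with an SD over members of 0.15, and 8 of them stood in the bone list. The 8 in no list of the report differed by -0.072 ± 0.043 (exact permutation p = 0.119). The small change of the 16 as a set argues against an even loss of bone and leaves fewer osteoblasts open. An even loss of marrow was weighed by B lineage genes minus neutrophil, erythroid and megakaryocyte genes, which differed by -0.22 ± 0.061 (exact permutation p = 0.0238). The B lineage list had already been seen to fall more than the neutrophil and erythroid lists, so this p-value is no independent support. Runner 2 (-2.07) lay above controls 2 (-2.10) and 3 (-2.09). Megakaryocyte genes alone came close to B lineage genes, so a part for marrow stays open. A candidate explanation is higher glucocorticoid signalling, known to lower osteocalcin and B cell precursors. On that account the induced genes would be higher, and they differed by 0.27 ± 0.054 (exact permutation p = 0.00794, unadjusted and the smallest these groups can give). The labelled contrast itself prompted that list, and it holds Pdk4, already seen to rise, so this is weak support. Whether there was such signalling, and whether running, handling or the hour of collection would have raised it, stays open. Clock genes that peak with Per minus those that peak with Arntl differed by 0.080 ± 0.082 (exact permutation p = 0.365), too imprecise to exclude another hour.

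Higher adipocyte and lipid synthesis genes in runners may come from fat tissue carried along with some runner samples. Of 8 fat cell genes outside the adipocyte list 7 were higher, with a mean difference of 0.17 ± 0.069 (exact permutation p = 0.0635), which neither excludes carried fat nor shows it. Ucp1, a brown fat gene, differed by 1.93 ± 0.54, but Cox8b by -0.12 ± 0.14 and Pparg by -0.020 ± 0.083. Lipid synthesis genes minus 7 genes of adipocyte identity differed by 0.023 ± 0.089 (exact permutation p = 0.778), similar mean rises that carried fat could give. Array by array this difference ran from 1.30 in runner 1 to 1.70 in runner 2, so the sets did not rise evenly. Against the mean of all arrays, runner 1 lay at -0.15 for lipid synthesis, within the controls, and at 0.048 for adipocyte identity, above every control. Runners 3 and 5 were the highest arrays in both sets. Adipoq, abundant in fat, differed by 0.084 ± 0.097 and Lep by 0.074 ± 0.077, less than Fabp4 and Cidec, which leaves a change within cochlear cells open as well.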
